A study of Sebastes schlegelii with 3 samples.

How the data were processed

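Ovarian stroma of the black rockfish (Sebastes schlegelii), a fish that bears live young, was profiled by droplet single-cell RNA sequencing. There were 3 libraries, 1 from each reproductive state: unfertilized, normal-gestation and abnormal-gestation. Per the labels' protocols, oocytes or embryos were dissected away, the stroma was digested with trypsin and EDTA, and libraries were made with the 10x Genomics 3′ v3.1 kit, which marks each captured RNA molecule with a unique molecular identifier (UMI).

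The authors deposited raw UMI counts per gene and cell barcode. The counts came from Cell Ranger, which is named as version 8.0.1 per the file headers and as version 9.1.0 per the submitters' processing notes. The genome build and annotation are not given in the sources used here. The lowest barcode total was 500 UMIs in every library, so barcodes below that were not analysed here. The 24133 features carry identifiers of gene predictions, and the files do not pair these identifiers with gene names. The gene lists and cell type markers fixed before the data were examined therefore had nothing to match, no mitochondrial limit was applied, no erythroid cells were removed, and clusters are given by number.

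Kept cells had at least 500 UMIs and at least 200 genes and were not called as doublets by Scrublet, run per library in scanpy 1.11.5 with an expected rate of 0.8% per 1000 barcodes. The caller marked 0.0524% of unfertilized barcodes, against an expected 4.58%. It marked 29.7% of normal-gestation barcodes (expected 24.3%) and 8.92% of abnormal-gestation barcodes (expected 23.8%). The filter therefore acted unequally on the 3 libraries. Why was not tested: the caller may have failed, or doublets may have been removed before the counts were deposited.

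As planned, all kept cells were first clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within each library, and 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1.0 were used, with no integration. Because nearly every cluster then lay within 1 library, each library was clustered on its own by the same steps. This clustering was not in the plan, and the rule that joined these clusters was chosen after seeing the data. UMIs were summed per cluster, log2(CPM + 10) was centred within each library (CPM, UMI counts scaled to the same total), and clusters were joined by average linkage at a correlation of 0.5 over the 3000 most variable genes with at least 500 UMIs. The results are called matched groups, numbered by mean share. Matched groups under an alternative were paired 1 to 1 with the main ones, so a part that split off counted as lost.

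With 1 library per state there is no test, p-value or standard error. Shares of cells carry exact Clopper-Pearson 95% intervals. The shares of 1 library add up to a fixed total, so a larger share of 1 group lowers those of the others. Ratios of CPM of summed UMIs carry exact conditional binomial 95% intervals. The correlations across genes used genes with a mean of at least 20 CPM, and genes are not independent replicates; their 95% ranges come from 100 Poisson resamplings, centred on the value. All of these cover counting error only. Comparisons within a matched group needed at least 100 cells in both libraries, with sums thinned to 100000 UMIs per side, and random equal parts of the cells of 1 library served as the reference. A cell was called high in the 20 leading genes of a group if they took at least 0.5 of the lowest library median of their share of UMIs in the group's cells, and at least 5 UMIs. This limit depends on depth.

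Identifiers were named by a rule fixed before the data were examined, shortened because no names were given: the 2 highest and the 2 lowest CPM ratios per comparison among features with at least 100 CPM and 100 UMIs in the higher library. A floor of 3 counts was used for ranking. The planned restriction to features with a gene symbol and the exclusion of mitochondrial and ribosomal protein genes were not possible.

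The scripts were tested on simulated data. For the normal-gestation against unfertilized comparison, intervals were checked for 10136 genes with at least 100 UMIs in the unfertilized library. Of these, 100 genes were changed 2-fold and 100 were changed 4-fold. The intervals held the true value for 97.0% and 95.0% of them. For abnormal-gestation against normal-gestation, with 11655 genes and again 100 changed by each fold, these were 94.0% and 96.0%. The counts were drawn with Poisson error alone, which the intervals assume. Coverage near 95% therefore checks the calculation and not how the intervals handle other variation. In a simulation of 10 cell types in 3 libraries, with library shifts of 0.7 (SD, log2) in every one of 24133 genes, joint clustering gave 29 clusters, of which 29 lay within 1 library. The matching gave 10 groups with an adjusted Rand index of 1 against the simulated types. The types were profiles of normal-gestation matched groups, with 150 cells per library at about 1600 UMIs each. All types of a library had the same shift, which centring within the library removes. The simulation therefore does not show how the matching handles shifts that differ between groups, or uneven cell numbers and depth.

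The alternatives set before the data were examined covered the UMI minimum, doublet removal, Leiden resolution and, for expression, scaling, the weight of each cell and the depth per cell. Further ones, chosen after seeing the data, covered the matching rule, equal cell weights in the matching, centring within each library, joint clustering at equal depth, the doublet rate, barcodes of at least 50000 UMIs and matched group 7.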

Results

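The stroma of the black rockfish ovary was compared between an unfertilized ovary, a normal gestation and an abnormal gestation, to describe its cells and their transcripts across reproduction. The unfertilized library held 5724 barcodes and 22014000 UMIs, the normal-gestation library 30347 barcodes and 65820178 UMIs, and the abnormal-gestation library 29751 barcodes and 72666818 UMIs. After filtering, 5686, 21322 and 27096 cells were kept, with medians of 2809.5, 1591.5 and 1611.5 UMIs. Each state was 1 library, so no difference below has a replicate check, and state, animal and library cannot be separated.

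Clustered together, the cells of the 3 libraries hardly mixed. Of 33 clusters, 31 drew at least 95% of their cells from 1 library, and these held 99.5% of all kept cells. A cluster of this kind may be a library rather than a cell type. When each library was clustered on its own and clusters were joined by their profiles relative to their own library, 15 matched groups were found. Groups 1, 2, 3, 4, 7, 8 and 10 had a cluster in every library. Over the library pairs, correlations of centred profiles ranged from 0.779 to 0.899 in groups 1 to 4, from 0.656 to 0.916 in group 7, from 0.551 to 0.686 in group 8 and from 0.659 to 0.799 in group 10. Group 10 was not stable: it was joined with group 4 at a correlation of 0.4, had no counterpart at a Leiden resolution of 0.5, and lost its unfertilized cluster on 1 of the 2 gene sets. That cluster correlated with a normal-gestation cluster of group 4 (0.672) as well as with that of group 10 (0.665), so the shares of group 10 are not compared.

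The first comparison set normal gestation against the unfertilized ovary. Group 1 made up 39.7% (38.5 to 41.0) of unfertilized cells and 24.0% (23.4 to 24.6) of normal-gestation cells. Group 2 made up 20.5% (19.4 to 21.5) and 33.3% (32.7 to 33.9). The difference in group 1 was -15.7 percentage points, but -5.23 at a Leiden resolution of 0.5, so its size depended on how finely cells were clustered. Cells high in the 20 leading genes of group 1 were nearly as frequent in both libraries, at 33.9% of unfertilized and 32.3% of normal-gestation cells. For group 2 these were 20.2% and 29.9%, in the direction of its shares. The limit for a high cell depends on depth. Group 4 showed no stable difference, at 17.0% (16.04 to 18.0) of unfertilized cells and 3296 of 21322 normal-gestation cells (14.98% to 15.95%): the direction turned at a Leiden resolution of 2.0 (15.1% and 15.51%), and when clusters were joined at a correlation of 0.6 or matched on 1 of the 2 gene sets. The difference of -1.55 percentage points became larger with at least 1000 UMIs per cell (-3.13) and with doublet calls kept (-5.52). Group 8, in which a single gene reached 398681 CPM in the unfertilized library, held 10.1% (9.36 to 10.9) of unfertilized and 1.90% (1.73 to 2.10) of normal-gestation cells. This pairing was not stable: no normal-gestation cell stayed in the group with doublet calls kept, when clusters were joined at 0.6 or on 1 of the 2 gene sets, and the normal-gestation cluster correlated better with an unfertilized cluster of group 1 (0.590) than with that of group 8 (0.527). The shares of group 8 are therefore not compared.

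Groups 5 and 6 had clusters in both gestation libraries and none in the unfertilized library. Group 5 held 6.66% (6.32 to 6.998) of normal-gestation cells and group 6 held 9.20% (8.81 to 9.59). Cells with a high level of the 20 leading genes were nevertheless present in the unfertilized library, 33 cells (0.580%) for group 5 and 11 cells (0.193%) for group 6. Group 9 held 6.35% (5.73 to 7.01) of unfertilized cells and had no cluster in either gestation library, where 38 normal-gestation and 85 abnormal-gestation cells had a high level of its leading genes. Groups 5 and 9 were not unrelated: the normal-gestation cluster of group 5 and an unfertilized cluster of group 9 were each other's best match between these libraries, at 0.458, below the 0.5 needed to join. They also stayed apart when clusters were joined at 0.4. Group 12, found only in abnormal gestation (464 cells), was related to group 9 in a similar way. Its cluster and the same group 9 cluster were each other's best match between the unfertilized and abnormal-gestation libraries, at 0.424. Of the unfertilized cells, 312 (5.49%) were high in the 20 leading genes of group 12. Group 9 may therefore have a relative in gestation that the joining rule kept apart.

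**Figure D1:**
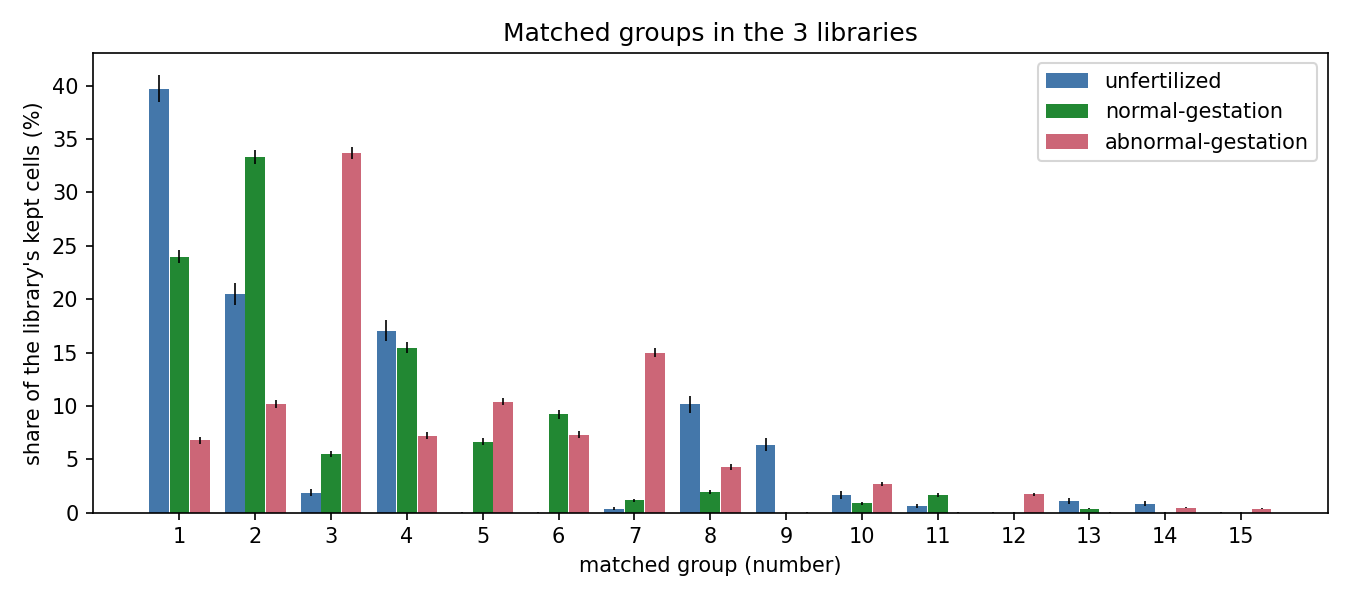
Share of each library's kept cells (y axis, percent) in each of the 15 matched groups (x axis), with bars coloured by library and exact 95% binomial intervals that cover counting error only. Group 3 held 33.7% of abnormal-gestation cells and 5.50% of normal-gestation cells.

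Over all kept cells, the identifiers with the highest ratios in normal gestation were evm.TU.Chr22.166 and evm.TU.Chr10.1068. The first had 10122 UMIs (246 CPM) in normal gestation against 2 UMIs in the unfertilized library, a ratio of 2700 (747 to 22299). The second had 4504 UMIs (109 CPM) against 2, a ratio of 1202 (332 to 9924). Both had their highest normal-gestation level in group 5, which had no unfertilized cluster, so these ratios include the difference in cell composition. Even the lowest normal-gestation group (22.3 and 7.95 CPM) lay above the highest unfertilized group (2.25 and 0.269 CPM); whether RNA from group 5 in other cells gave this was not tested. The lowest ratios belonged to evm.TU.Chr7.206_evm.TU.Chr7.205, 59.8-fold lower (47.1 to 77.0) in normal gestation, and evm.TU.Chr23.650, 53.9-fold lower (45.9 to 63.6). Both were highest in group 9 of the unfertilized library, at 1199 and 2404 CPM. In abnormal gestation both were highest in group 12, at 10.0 and 1167 CPM. Group 9 had no normal-gestation cluster, so these ratios also include the difference in cell composition.

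Within matched groups the libraries also differed. Across genes, r between normal-gestation and unfertilized profiles was 0.623 in group 1, 0.635 in group 2, 0.542 in group 3, 0.571 in group 4 and 0.528 in group 8. Values of group 8, here and in the other comparisons, rest on its unstable pairing. Random equal parts of the cells of 1 library at the same depth gave 0.7997 to 0.868. The log2 ratios of 2910 genes correlated between groups with a median r of 0.623 over 10 pairs of groups. Random parts of the cells within 1 library, where nothing differs, gave a median r of -0.00351 in normal gestation and 0.0136 in the unfertilized library. All pairs of groups share the same 2 libraries, so a difference of a whole library enters every group. Over all kept cells, with all their UMIs, r was 0.773 (0.772 to 0.774), which is not comparable with the thinned values within groups. With all UMIs, r within groups ran from 0.623 in group 8 to 0.771 in group 1.

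The second comparison set abnormal against normal gestation. Group 3 made up 33.7% (33.1 to 34.2) of abnormal-gestation cells and 5.50% (5.19 to 5.81) of normal-gestation cells, a difference of 28.2 percentage points. Cells high in its 20 leading genes were 48.0% of abnormal-gestation cells (13002 of 27096) and 5.30% of normal-gestation cells. In abnormal gestation such cells thus also lay in other groups. Whether free RNA, doublets or the limit's dependence on depth gave this was not tested here. Groups 1, 2 and 4 had lower shares in abnormal gestation: 6.76% (6.47 to 7.07), 10.2% (9.83 to 10.6) and 7.22% (6.92 to 7.54), against 24.0%, 33.3% and 14.98% to 15.95% in normal gestation. The difference in group 1, -17.2 percentage points, was -7.54 with doublet calls kept and -9.94 with at least 1000 UMIs per cell, since the normal-gestation share was then 13.97% and 16.3%. That in group 4, -8.24, was -3.61 and -4.80 under the same settings, with normal-gestation shares of 10.9% and 12.2%. Group 5 was at 10.4% (10.04 to 10.8), a difference of 3.75 that was 7.44 with at least 1000 UMIs per cell and 2.46 with doublets removed at the expected rate. Group 6 was at 7.30% (6.997 to 7.62), and its difference of -1.89 was -3.08 with doublet calls kept and turned to 0.896 with at least 1000 UMIs per cell. Doublet calls removed 29.7% of normal-gestation and 8.92% of abnormal-gestation barcodes before these shares were taken. The larger shares of groups 3 and 7 in abnormal gestation also lower the shares of all other groups. A lower share of group 1, 2, 4 or 6 therefore does not show that such cells were fewer. Differences were not recomputed without groups 3 and 7, and their direction, as in group 6, could then change.

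Group 7 held 14.97% (14.5 to 15.4) of abnormal-gestation cells, and 3259 of these 4056 cells had under 1000 UMIs. With at least 1000 UMIs per cell its share was 4.4%. Its counterpart in normal gestation, 1.14% (1.002 to 1.29), rested on 2 barcodes of at least 50000 UMIs, which held 38.7% of that cluster's UMIs. In the unfertilized library 2 such barcodes among 21 held 87.4% of the UMIs of group 7, and its correlation with abnormal gestation, 0.916, was 0.811 without barcodes of that size and 0.798 with every cell weighted equally. The correlation between the gestation profiles of group 7 was 0.6999 from summed UMIs and 0.122 with every cell weighted equally, and no normal-gestation cell stayed in the group under that weighting. The normal-gestation share of group 7 is therefore not compared further.

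Over all kept cells, evm.TU.Chr20.417 and evm.TU.Chr15.458 had the highest ratios in abnormal gestation. The first had 132 CPM against 0.826 CPM, a ratio of 160 (114 to 231), and lay at 85.9 CPM in the unfertilized library, so it was low in normal gestation compared with both other libraries. The second had 34448 CPM against 416 CPM, a ratio of 82.7 (81.5 to 84.0), with 847 CPM in the unfertilized library, and took 3.45% of all abnormal-gestation UMIs. In abnormal gestation evm.TU.Chr15.458 was highest in group 3, at 62970 CPM against 1940 CPM in group 3 of normal gestation, and its lowest level in any group was 8513 CPM. The lowest ratios belonged to evm.TU.Chr14.790, 22.1-fold lower (20.5 to 23.9), and evm.TU.Chr8.962, 19.9-fold lower (18.9 to 21.0). Both were highest in group 2 of normal gestation, at 508 and 973 CPM. Group 2 had a lower share in abnormal gestation, so these ratios include the difference in cell composition. Within group 2 of abnormal gestation, evm.TU.Chr14.790 was at no more than 80.0 CPM and evm.TU.Chr8.962 at 163 CPM.

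**Figure D2:**
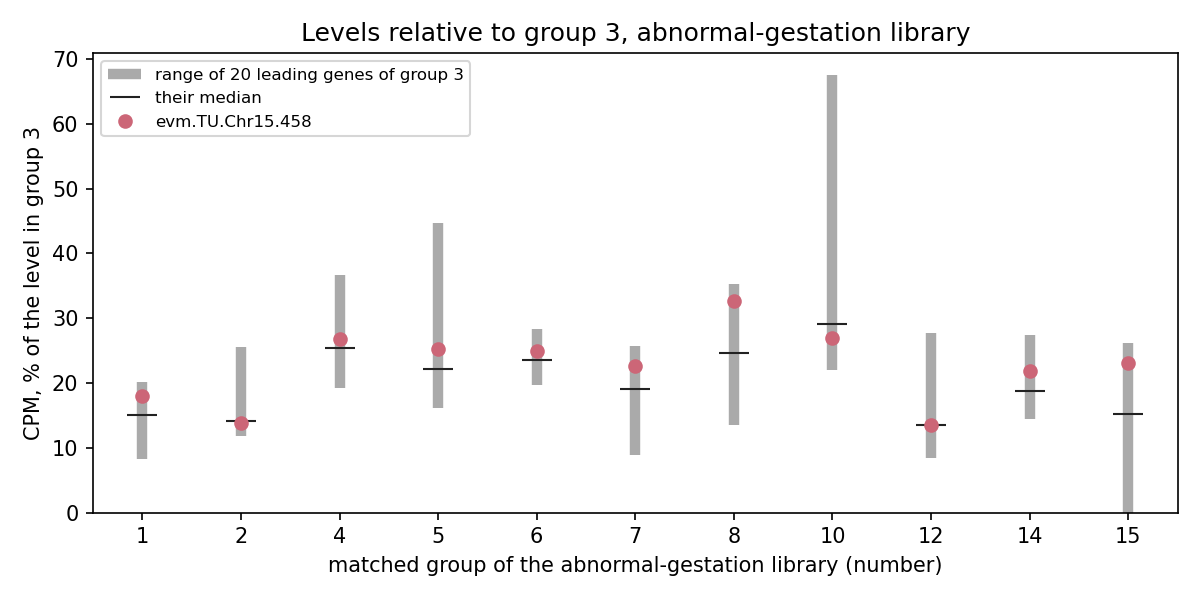
CPM in each other matched group of the abnormal-gestation library (x axis) as a percent of the level in group 3 (y axis), for evm.TU.Chr15.458 (points) and for 20 leading genes of group 3 (bars, lowest to highest; dashes, median). The points lie between 13.5% and 32.7%, inside the range of the leading genes in all 11 groups.

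Within matched groups, r between the gestation libraries was 0.714 in group 1, 0.751 in group 2, 0.694 in group 3, 0.717 in group 4, 0.763 in group 5, 0.726 in group 6, 0.587 in group 8 and 0.676 in group 10, against 0.811 to 0.854 for equal parts of 1 library in these groups. The log2 ratios of 3358 genes correlated between groups with a median r of 0.730 over 36 pairs, and 0.751 over 28 pairs without group 7. Random parts of the cells within 1 library gave -0.00215 in abnormal gestation at the median. Over all kept cells, with all their UMIs, r was 0.812 (0.812 to 0.813), which is not comparable with the thinned values within groups. With all UMIs, r within groups ran from 0.712 in group 8 to 0.908 in group 5.

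**Figure D3:**
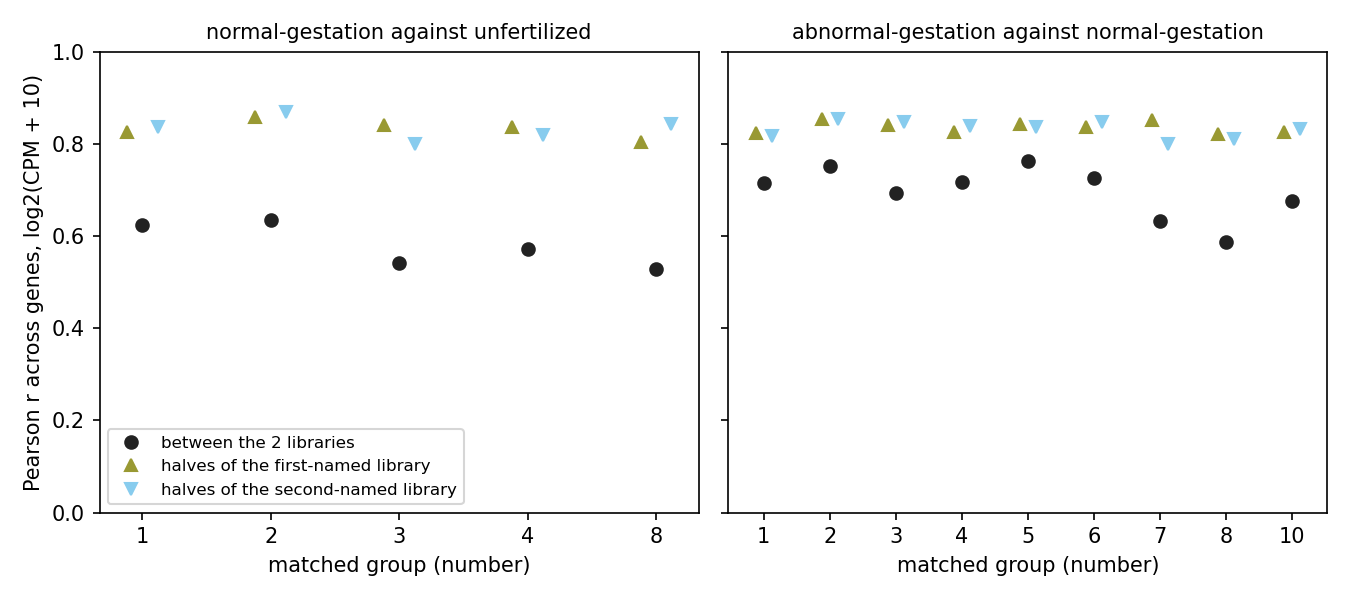
Pearson r across genes of log2(CPM + 10) (y axis) between libraries within each matched group (x axis, circles), beside random equal parts of the cells of 1 library (triangles), at 100000 UMIs per side. The circles lie below both triangles in every group shown; the group 7 circle of the right panel includes the normal-gestation cluster that rested on 2 barcodes.

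The unfertilized and abnormal-gestation libraries were the least alike, with r of 0.664 (0.664 to 0.665) over all kept cells. Group 1 held 39.7% of unfertilized and 6.76% of abnormal-gestation cells, and group 3 held 1.85% (1.51 to 2.23) and 33.7%. Within groups, with sums thinned as before, r was 0.540 in group 1, 0.619 in group 2, 0.482 in group 3, 0.534 in group 4 and 0.481 in group 8. With all UMIs, as used over all kept cells, it ran from 0.573 in group 8 to 0.736 in group 2.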

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

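The matching of clusters and the settings on expected doublet rate, joining correlation, split gene sets, equal cell weights, RNA-rich barcodes, centring, joint clustering of thinned cells and group 7 were chosen after seeing the data. The clustering of each library on its own was likewise not planned. The number of clusters lying within 1 library stayed within 1.5 times of 31 under the 6 settings run (21 to 39). Of the 14 share differences described, 12 kept their sign under all 12 settings, though sizes moved. This count leaves out groups 7, 8 and 10, which were set aside after their pairing proved unstable, so it does not measure the stability of all groups. Several of the settings reused the main clusters and are not independent. Centring, which does not compare like groups, is among the 12. Group 4, normal-gestation minus unfertilized (-1.55), turned to 0.380 at resolution 2.0, 0.298 when joined at 0.6 and 0.298 on 1 of the 2 gene sets. Group 6, abnormal minus normal gestation (-1.89), turned to 0.896 with at least 1000 UMIs. The causes of these moves were not tested.

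For group 1, normal-gestation minus unfertilized, the difference of -15.7 percentage points became -5.23 at resolution 0.5, -11.3 at resolution 2.0, -18.4 at the expected doublet rate, -11.5 when joined at 0.6, -11.5 with equal cell weights and -31.7 with genes centred within each library. For group 2 (12.8) it was 17.8 with at least 1000 UMIs, 11.1 with doublet calls kept, 15.8 and 15.1 at resolutions 0.5 and 2.0, 16.4 at the expected doublet rate and 25.2 with centring. For group 3, abnormal minus normal gestation (28.2), it was 34.2 with at least 1000 UMIs, 22.7 with doublet calls kept, 26.3 and 25.7 at resolutions 0.5 and 2.0, 27.2 at the expected doublet rate, 26.8 when joined at 0.6 and 22.8 with centring. For group 2 (-23.1) it was -24.6 with at least 1000 UMIs and -25.1 with centring. For abnormal-gestation minus unfertilized, group 1 (-33.0) was -26.5 with at least 1000 UMIs, -24.0 with doublet calls kept, -22.5 and -23.4 at resolutions 0.5 and 2.0, -23.6 when joined at 0.6 and -23.6 with equal cell weights, and group 3 (31.8) was 36.7, 27.1, 28.1, 29.4, 30.6 at the expected doublet rate, 30.4 when joined at 0.6 and 22.8 with centring, the first 4 in the same order of settings. After centring, 21 of 30 joint clusters still lay within 1 library and 46.6% of cells stayed in their matched group, so its shares do not compare like groups; abnormal minus normal gestation was then -0.065 in group 1 and -0.008 in group 4, and normal-gestation minus unfertilized -15.92 in group 4 and 0.098 in group 5. Of 540 shares of single groups, 137 left their counting interval.

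The r over all kept cells, in the order normal-gestation against unfertilized, abnormal against normal gestation, abnormal-gestation against unfertilized, was 0.770, 0.810 and 0.666 with doublet calls kept, 0.740, 0.792 and 0.581 with cells weighted equally, 0.770, 0.810 and 0.666 over all deposited barcodes, and 0.757, 0.823 and 0.644 without group 7. With at least 1000 UMIs the last pair became 0.818 and 0.670, and at the expected doublet rate 0.811 and 0.668. The median r within groups with all UMIs (0.708, 0.868 and 0.663) was 0.710, 0.872 and 0.673 with at least 1000 UMIs, 0.659, 0.859 and 0.611 with equal weights, and 0.655, 0.867 and 0.616 with cells thinned to 1000 UMIs. With size factors the first and last were 0.709 and 0.651. The 8 named identifiers kept the sign of their ratios in all 56 values, of which 15 left the counting interval.

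Planned settings on the mitochondrial limit, erythroid cells, clusters named by markers and gene lists were not run, because no gene names were given. No paired analysis was possible because each state is 1 library. Counts of 2 UMIs limit the ratios of evm.TU.Chr22.166 and evm.TU.Chr10.1068 to wide intervals.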

Other observations

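The tests on depth, on group 7 and on evm.TU.Chr15.458 were chosen after related values had been seen; the tests on free RNA in all groups and on neighbouring gene models were written before their results.

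Barcodes with very high UMI totals were few. At least 50000 UMIs were found in 4 unfertilized, 2 normal-gestation and 8 abnormal-gestation barcodes, of which 2, 2 and 8 fell in group 7. They held 87.4%, 38.7% and 24.1% of the UMIs of that group.

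The separation of cells by library was not removed by equal depth. The 40462 kept cells with at least 1000 UMIs were thinned to 1000 UMIs, and the other kept cells were left out. Of 26 clusters, 23 still lay within 1 library, which argues against depth as the whole cause in these cells. Free RNA of each library stays open. The 200 genes most evenly higher in abnormal gestation had a median level of 0.405 of the library total (quartiles 0.346 and 0.456), each taken in the group where it was lowest. This lies above the 0.187 seen at most for 7 genes restricted to group 6 and below the 0.538 reached at most by the leading genes of group 3 in other groups. Within each of the 8 other groups compared, the median of the 200 genes was above the leading genes of group 3, by most in group 7 (4.31 against 0.346) and by least in group 5 (0.443 against 0.412). Free RNA from group 3 at the level of those leading genes would thus fall short of the 200 genes in these groups. Those leading genes cannot measure free RNA from other groups, such as group 7, where the 200 genes were highest. The comparison therefore does not count against free RNA as such. Free RNA is also not excluded because the 200 genes were picked for a high ratio in every group and the levels come from 1 library. The bound set beforehand used the restricted genes alone and would have excluded free RNA, but those 7 genes all come from 1 group, and group 3 gives a higher level. With 1 library per reproductive state, animal, batch and state cannot be told apart.

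What the shallow barcodes of group 7 in abnormal gestation hold (3259 under 1000 UMIs) stays open. They correlated better with the RNA-rich barcodes than with the library without group 7, by 0.186, and in a non-negative mix of profiles the RNA-rich one took a weight of 0.533. The 91 shallow normal-gestation barcodes of group 7 went the other way. Their r was 0.214 with the RNA-rich barcodes and 0.769 with the library without group 7, and the weight was 0.0712. Neither value of abnormal gestation decides between free RNA of the library and RNA shed by RNA-rich cells, because group 7 was formed by likeness of profiles and was taken out of the comparator. The leading genes of group 7 were widespread in that library: 24979 of 27096 abnormal-gestation cells (92.2%) were high in 20 of them. The limit was low, at 0.5 of a median share of 0.153% and at least 5 UMIs, and it depends on depth, so this does not decide either. Small cells of the same kind were not tested.

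The level of evm.TU.Chr15.458 in the other abnormal-gestation groups was 13.5% to 32.7% of that in group 3, and in 0 of 11 groups lay above all 20 leading genes of group 3. It lay above the lowest of them in 11 of 11 groups, with a median percentile of 80, so it stood rather high among them. The outcome written for free RNA from group 3, a level within the range of these genes, was thus met. A further condition, not part of that outcome, was that the 20 genes keep nearly 1 ratio. It was not met, since the highest was 2.62 times the lowest at the median over groups. This spread does not count against a single source, because whether other groups express some of these genes themselves was not tested. The range is also wide, so lying in it does not settle the question. Whether free RNA from group 3 accounts for the presence of evm.TU.Chr15.458 in every group stays open. Free RNA would leave the difference within group 3 itself, 32.5-fold between the gestation libraries, unexplained; that state, animal and batch are confounded keeps its origin open.

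A hypothesis that neighbouring gene models differ together between the gestation libraries was not settled: over 1527 pairs of consecutive models the log2 ratios correlated with r = 0.124, above the highest of 10000 shuffles of the pairs (0.107 in size) but between the bounds set beforehand. The correlation is thus weak but beyond what shuffled pairs gave, and gene models are not independent replicates.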
